A study of Caenorhabditis elegans with 10 samples.

How the data were processed

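DamID-seq was used on Caenorhabditis elegans L4 larvae, per the labels. In this assay a chromatin protein is fused to the bacterial DNA adenine methyltransferase Dam, which methylates adenine in GATC sites near the places the fusion visits. Methylated fragments are then isolated with the methylation-sensitive enzymes DpnI and DpnII, amplified and sequenced. GFP fused to Dam serves as the control for accessibility of the chromatin. Per the labels' protocols, synchronised embryos were grown for 48 h at 20 °C and 200 ng of genomic DNA entered each library.

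The series holds 10 libraries in 5 groups of 2. The groups are HPL-1-Dam in intestine, HPL-2-Dam in intestine, HPL-2-Dam in hypodermis, GFP-Dam in intestine and GFP-Dam in hypodermis. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures.

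The 3 deposited files are peak lists, 1 for each HPL fusion and tissue. Their names say that each was called on an average profile relative to Dam, at an FDR threshold of 0.05. Replicates had therefore been combined by the authors before peaks were called, and no list holds values per replicate. The number of libraries averaged is not stated, and the sequencing depth of each library and the peak caller are not given in the sources used here. Bowtie2 2.3.4, SAMtools 1.9 and R 3.4.3 were used with the WBcel235/ce11 assembly, per the submitters' processing notes. Each line of the deposited lists gives other values besides the score, namely the chromosome, start and end of a peak. The score of each peak is the authors' own, on a scale the deposited lists do not state, and it was used only to rank and describe peaks within 1 list. Each peak also carries the authors' FDR, which reached at most 0.0367, 0.0362 and 0.0352 in the deposited HPL-1 intestine, HPL-2 intestine and HPL-2 hypodermis lists. The GFP-Dam libraries enter only through the authors' comparison, and no signal of their own was analysed here.

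Processing of this kind affects the measurements in several ways. Binding is resolved only to GATC fragments, so peak edges are those of fragments. A peak means a higher value than GFP-Dam in the same tissue, so a region with high GFP-Dam methylation is harder to call. The averaging removes the replicate error, so no value below carries an error between animals or cultures, and each p-value describes how these 3 lists lie on the genome. The labels do not pair libraries with sequencing batches.

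Peaks were matched to a RefSeq gene table of the WBcel235 assembly with 46890 genes, of which 19971 are protein coding. The table gives gene starts and ends but no strand, exons, repeats or chromosome lengths. The planned window of 1 kb upstream of a gene could therefore not be placed, and a gene was called bound when a peak overlapped its body by at least 1 bp. Gene body or 1 kb on either side was added as an alternative. Shares of exons, introns and repeats, a window around the transcription start and a 2 kb upstream window, all planned, were not run. The extent of a chromosome was taken as the furthest gene or peak end, 100.27 Mb over the 6 chromosomes.

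Peaks of the lists were called shared when they overlapped by at least 1 bp. The chance level was set by rotating all peaks of a list by a random offset within each chromosome, which keeps their widths and spacing, in 10000 draws. This circular permutation, called rotation below, gave two-sided tests that cannot give a p below 0.0002. For the number of peaks per chromosome, all peaks were instead rotated by a single random offset over the chromosomes joined end to end. Rotated peaks were not kept on GATC fragments or on sequence to which reads can be aligned, so rotation does not model these limits. Arms were the outer parts of each chromosome after division into 3 equal parts, assigned by peak midpoint. Arm shares were compared between lists by Fisher's exact test and by an exact sign-flip test over the 6 chromosomes. Both were added after the lists had been seen. Also added then were the tests of HPL-1 peaks against both HPL-2 lists and of HPL-2 hypodermis peaks against both intestine lists. For the arms, the whole-list tests were first adjusted with the tests per chromosome, 21 in all, and then as a family of 3, a change made after the values had been seen. Genomic context was the share of covered bp in protein-coding gene bodies, within 1 kb of them on either side in place of the planned upstream window, or elsewhere.

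In all, 25 gene lists were tested against the rotation in each peak list, 75 tests in 1 family. The lists included cuticle collagens, muscle genes and C-type lectins. Genes bound in only 1 of the lists compared were tested by Fisher's exact test, 25 tests per comparison. Scores of shared and other peaks were compared with a permutation test of 100000 resamples, which cannot give a p below 1e-05. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Confidence intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only, and neighbouring peaks or genes are not independent.

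Named genes follow a fixed rule. Per comparison, they are the protein-coding genes with a 3 or 4 letter symbol under the 10 highest scoring peaks that are shared, ranked in the HPL-2 intestine list, or present in 1 list only. For each gene list that passed, the 4 bound members under the highest scoring peaks were added, and hpl-1 and hpl-2 were always reported. The groups, the gene lists and this rule were set before the data were examined. So were the tests and alternatives, except those named as added or as chosen after the data had been seen.

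The code was tested on simulated lists. Among 1500 gene list tests on rotated lists with no effect, 1.93% had an unadjusted p below 0.05 and 0 passed after adjustment. These simulations used 1000 rotation draws, fewer than for the deposited lists, so their smallest possible p was larger. Passing after adjustment was therefore harder than in the deposited lists, and the 0 says little about false calls. Of 60 overlap tests with no effect, 4 were below 0.05. The lists with no effect were made by the same rotation that the tests use. These rates therefore check the code and not whether rotation is a fair chance level for the deposited peaks. An overlap of 30% planted between lists was recovered as 31.9% (31.4% to 32.5%). With 40 collagen genes planted under peaks among 19971 protein-coding genes, the collagen list had an unadjusted p below 0.05 in 10 of 10 runs. That rule is looser than the adjusted p used for the deposited lists. Both comparisons between lists called the planted collagens after adjustment in 10 of 10 runs. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 were used.

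Alternatives covered a stricter FDR of 0.01, 50% of a peak covered or a gap of up to 1 kb in place of 1 bp, equal list sizes by score, rotation within each of the 3 parts of a chromosome, covered bp in place of peaks, arms as the outer parts of 4 in place of 3 equal parts, and Fisher's exact test in place of rotation. Peaks set to 500 bp around their midpoint, with and without equal list sizes, were added later for the tests of which list a list overlaps more. No sample was left out, and no comparison of replicates was possible.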

Results

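HPL-1 and HPL-2 are the C. elegans members of the heterochromatin protein 1 family, which bind methylated histone H3 lysine 9. Their fusions to Dam were expressed in the intestine (HPL-1 and HPL-2) or in the hypodermis, the epidermis that secretes the cuticle (HPL-2), and profiled in L4 larvae. Each group had 2 libraries, and each HPL group had a GFP-Dam control group of 2 libraries in the same tissue. The HPL-1 and HPL-2 intestine profiles shared the same control group. The data are 1 averaged peak list per HPL fusion and tissue, so the values below have no error between replicates.

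The HPL-1 intestine list held 1346 peaks over 955 kb, 0.952% of the genome, with a median width of 616 bp. The HPL-2 intestine list held 1665 peaks over 1357 kb, 1.35% of the genome, with a median width of 678 bp. The HPL-2 hypodermis list held 1572 peaks over 1744 kb, 1.74% of the genome, with a median width of 948 bp. Median peak scores were 0.66, 0.95 and 1.65 in this order, on the authors' scale. At an FDR of 0.01 or below, 723, 1083 and 935 peaks were left. Peaks overlapped the bodies of 966, 1221 and 1182 of 19971 protein-coding genes, and 178 genes were bound in all 3 lists.

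The first question was where HPL-1 and HPL-2 bind alike and apart within the intestine. Peaks of both proteins lay over the cuticle collagen gene col-87, the C-type lectin genes clec-126 and clec-250, the RIM-binding protein gene rimb-1 and the body wall muscle myosin gene unc-54, which stood under the 10 highest scoring shared HPL-2 intestine peaks. The peak over col-87 (chromosome II, 14090129 to 14092305) scored 2.68, that over clec-126 (II, 3519698 to 3521042) 2.5, that over rimb-1 (III, 1803310 to 1805614) 2.47, that over clec-250 (V, 18740449 to 18740864) 2.36 and that over unc-54 (I, 14856213 to 14857659) 2.2. Of the HPL-1 peaks, 375 of 1346 (27.9%, 25.5% to 30.3%) overlapped an HPL-2 intestine peak, 10.9 times the 2.55% given by rotation. In the other direction, 367 of 1665 HPL-2 intestine peaks (22.04%, 20.1% to 24.1%) overlapped an HPL-1 peak, against 2.06% by rotation. Both rotation tests, which are circular permutation tests, gave p = 0.0002, the smallest the draws can give. Both proteins were over 327 protein-coding genes, against 100.4 by rotation (3.26-fold, permutation p = 0.0002) and 59.1 for independent lists of these sizes. Part of this excess may come from the shared GFP-Dam intestine control, whose share cannot be measured from peak lists. Rotation does not keep peaks on GATC fragments, and the effect of this on the overlaps here and below was not tested.

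Among the 10 highest scoring HPL-1 intestine peaks without an HPL-2 intestine peak, 7 lay over a gene of the named kind. These were atfs-1, a transcription factor of the mitochondrial unfolded protein response (V, 14196255 to 14197324, score 1.37), the heavy spectrin gene sma-1 (1.35), the ribosomal S6 kinase gene rskn-1 (1.34), the adenylyl cyclase gene acy-1 (1.29), rips-1 (1.27), the edge of the collagen gene col-3 (1.25) and the F-box gene fbxa-185 (1.23). Among the 10 highest HPL-2 intestine peaks without an HPL-1 peak, 6 lay over such genes. They were the TIR-domain adaptor gene tir-1 (III, 3896268 to 3896717, score 2.62), the acyl-CoA-binding protein gene acbp-6 (2.29), gfrl-1 (2.24), the DNA primase gene pri-2 (2.17), the ion channel gene tric-1B.1 (2.03) and dpy-18 (2.01), which encodes a subunit of the collagen prolyl 4-hydroxylase. Scores were not compared between lists, since their scale is not stated. HPL-1 intestine peaks that overlapped HPL-2 intestine peaks had a median score of 0.72, against 0.65 for the other HPL-1 peaks, and the HPL-2 intestine medians were 1.15 and 0.91 (permutation p = 1e-05 each, the smallest possible). These shared peaks were also wider, with median widths of 685 against 609 bp in HPL-1 intestine and 816 against 631 bp in HPL-2 intestine.

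**Figure D1:**
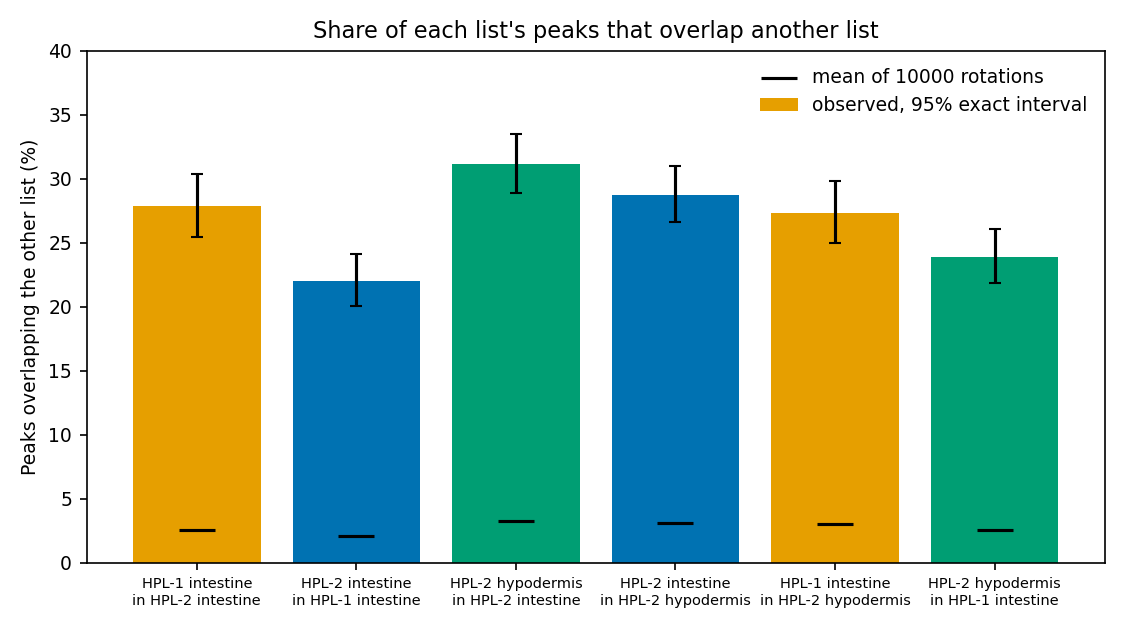
Percentage of the peaks of the first list named under each bar that overlap a peak of the second (y axis), coloured by first list, with exact 95% intervals as error bars; black marks are the means of 10000 rotations. The bars lie between 22.04% and 31.2%, and the marks between 2.06% and 3.24%.

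Gene groups separated the intestinal profiles. Cuticle collagens, the structural proteins of the cuticle, were bound by HPL-2 and not HPL-1 in 72 cases, by HPL-1 and not HPL-2 in 7 and by both in 8 (Fisher's exact test, adjusted p = 1.2e-09). Muscle genes followed the same direction, with 12 bound by HPL-2 only, 0 by HPL-1 only and 7 by both (exact test, adjusted p = 0.0123). Members of 3 large gene families went the other way. F-box genes, which encode substrate adaptors of ubiquitin ligases, were bound by HPL-1 only in 17 cases and by HPL-2 only in 2 (exact test, adjusted p = 0.000245), chemoreceptor genes in 29 and 13 (0.00308), and the substrate adaptor genes with MATH and BTB domains in 11 and 3 (0.0302). The muscle difference no longer passed at an FDR of 0.01 (exact test, adjusted p = 0.637), nor did that of F-box genes with 1 kb added on either side of genes (0.102). That of MATH and BTB genes no longer passed at an FDR of 0.01 (0.0515) and with genes under 1 peak counted once (0.161). C-type lectins, with 17 bound by HPL-1 only, 9 by HPL-2 only and 11 by both, did not pass (0.0661) but did at an FDR of 0.01 (0.0359) and with 1 kb added on either side of genes (0.00142).

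The next question was how HPL-2 binding differs between tissues. The genes under the highest scoring peaks found in both tissues were col-87, tir-1, clec-126, rimb-1, clec-250, acbp-6 and gfrl-1. In the hypodermis list, 490 of 1572 peaks (31.2%, 28.9% to 33.5%) overlapped an HPL-2 intestine peak, 9.62 times the 3.24% given by rotation. In the intestine list, 479 of 1665 peaks (28.8%, 26.6% to 31.01%) overlapped a hypodermis peak, against 3.11% by rotation. Both p-values were 0.0002, the smallest the draws can give. HPL-2 lay over 435 protein-coding genes in both tissues, against 119.1 by rotation (3.65-fold, permutation p = 0.0002) and 72.3 for independent lists.

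Top-scoring peaks of the hypodermis that were absent from the HPL-2 intestine list lay over pudl-2 (IV, 2834844 to 2835290, score 3.19), the chemoreceptor gene str-64 (2.83), the elongin C gene elc-2 (2.82), sdz-16 (2.79) and rgs-4 (2.75), a regulator of G protein signalling. Those over str-64, elc-2 and sdz-16 also overlapped HPL-1 intestine peaks. Intestine peaks absent from the hypodermis list lay over tric-1B.1 (II, 12264599 to 12265581, score 2.03), the hedgehog-related gene grl-16 (1.98), rad-54.B (1.92) and lido-7 (1.89). Shared peaks scored higher within each list, with medians of 1.81 against 1.59 in hypodermis and 1.15 against 0.9 in intestine (permutation p = 1e-05 each, the smallest possible). They were also wider, with medians of 1021 against 921 bp and 926 against 580.5 bp, and among peaks of like width the score difference in intestine fell from 0.25 to 0.139 (permutation p = 1e-05).

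Cuticle collagens gave the clearest difference between the tissues. HPL-2 lay over 74 collagen genes in intestine only, 2 in hypodermis only and 6 in both (odds ratio 0.0258, Fisher's exact test, adjusted p = 1.8e-18). F-box genes (28 in hypodermis only, 4 in intestine only, exact test, adjusted p = 7.8e-05), chemoreceptor genes (40 and 12, 0.000251) and MATH and BTB genes (11 and 1, 0.0168) were more often in the hypodermis list. The MATH and BTB difference no longer passed at an FDR of 0.01 (0.347) and with lists of equal size (0.089). Muscle genes did not differ detectably, with 14 bound in both tissues, 4 in hypodermis only and 5 in intestine only (exact test, adjusted p = 1.0). C-type lectins, with 26 in hypodermis only and 11 in intestine only, did not pass (0.0576) but did with 1 kb added on either side of genes (0.0155). Both comparisons use the HPL-2 intestine list. The differences of collagens and of F-box, chemoreceptor and MATH and BTB genes in this and the previous comparison are therefore not independent.

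**Figure D2:**
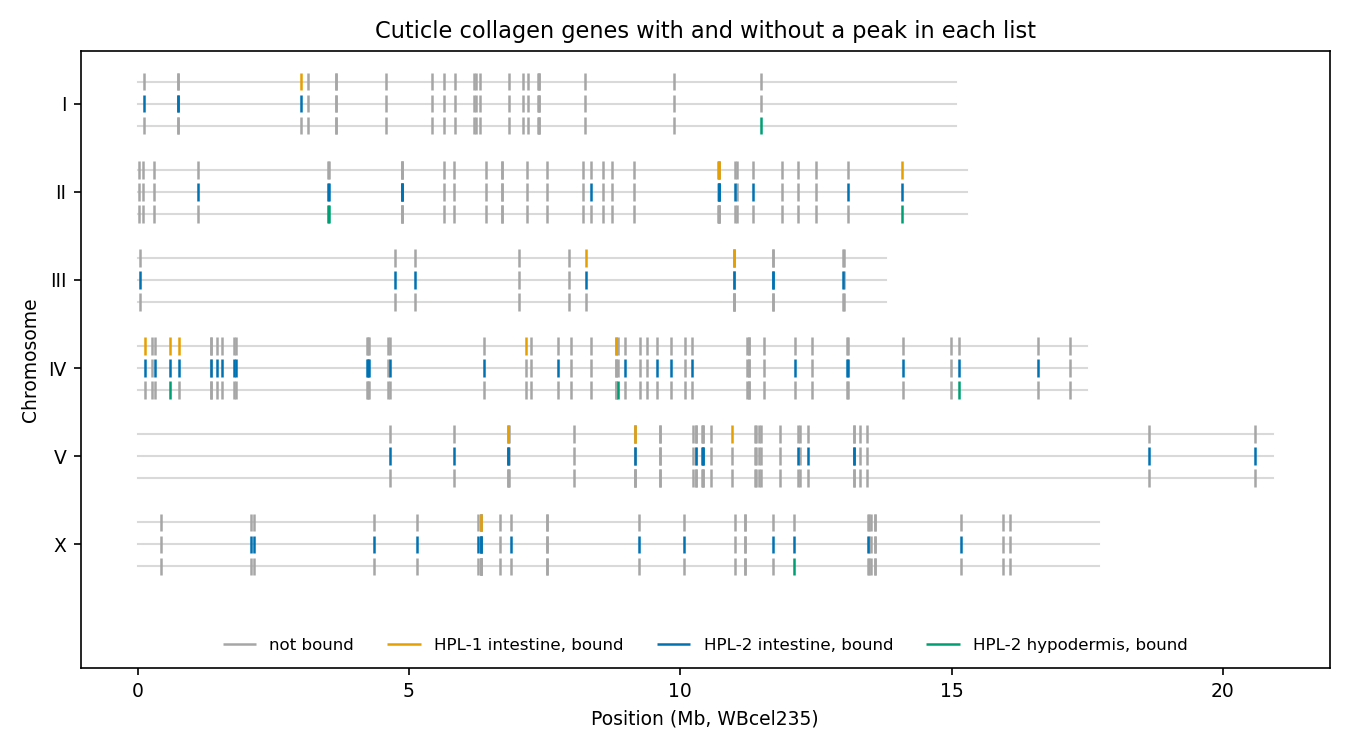
Positions of the 177 cuticle collagen genes (x axis, Mb) on the 6 chromosomes (y axis), with 1 line per peak list; coloured ticks are genes with a peak over their body and grey ticks those without. The HPL-2 intestine list covers 80 genes, spread over all 6 chromosomes, the HPL-1 intestine list 15 and the HPL-2 hypodermis list 8.

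HPL-1 in intestine and HPL-2 in hypodermis share neither tissue, fusion nor control group. Even so, peaks of both lay over elc-2, sdz-16 and fbxa-185, and 368 of 1346 HPL-1 peaks (27.3%, 25.0% to 29.8%) overlapped a hypodermis peak, 9.05 times the 3.02% given by rotation (permutation p = 0.0002, the smallest the draws can give). Of 1572 hypodermis peaks, 376 (23.9%, 21.8% to 26.1%) overlapped an HPL-1 peak. Both were over 306 protein-coding genes, against 93.6 by rotation and 57.2 for independent lists. All 3 lists met at 176 HPL-2 intestine peaks, 10.6% of that list, and 57.8% of HPL-1 intestine, 59.8% of HPL-2 intestine and 56.0% of HPL-2 hypodermis peaks overlapped neither of the other lists.

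Whether a list lay closer to the same protein in the other tissue or to the other protein in the same tissue changed with the number and width of the peaks entered. Of HPL-2 intestine peaks, 303 overlapped an HPL-2 hypodermis peak but no HPL-1 peak and 191 an HPL-1 peak but no hypodermis peak, a difference of -6.73 percentage points for HPL-1 minus HPL-2 hypodermis (exact McNemar test, p = 5.3e-07). The hypodermis list covers more sequence, and rotation gave 3.11% with it against 2.06% with HPL-1, so that the overlap was 9.24 times rotation with HPL-2 hypodermis and 10.7 times with HPL-1. With every peak set to 500 bp around its midpoint the difference was -2.46 points (exact p = 0.0573), and with lists of equal size as well it was -0.297 points (exact p = 0.877). Hypodermis peaks overlapped HPL-2 intestine peaks only in 315 cases and HPL-1 peaks only in 201 (exact p = 5.9e-07). That difference was 3.31 points with peaks of 500 bp (exact p = 0.0149) and did not pass with lists of equal size as well (0.892 points, exact p = 0.569). HPL-1 peaks showed no detectable difference, with 200 overlapping only HPL-2 in intestine and 193 only HPL-2 in hypodermis (0.52 points, exact p = 0.762). At an FDR of 0.01 the HPL-1 peaks did differ, by 5.81 points toward the intestine (exact p = 0.00603), and with 50% of the peak covered the difference was -0.297 points (p = 0.878).

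Over the whole genome HPL-2 was concentrated on chromosome arms in both tissues. Of the HPL-2 intestine peaks 88.3% (86.7% to 89.9%) and of the hypodermis peaks 88.4% (86.7% to 89.9%) lay in the outer parts of the chromosomes, against 66.7% and 66.6% by rotation (permutation test, adjusted p = 0.0006 for each). For single chromosomes every HPL-2 share was above rotation but 0 of 12 passed (permutation test, lowest adjusted p = 0.252), and X had the lowest shares, 78.7% in intestine and 75.2% in hypodermis. Of the HPL-1 intestine peaks 74.1% (71.7% to 76.5%) lay there, against 66.6% by rotation, which did not pass (permutation test, adjusted p = 0.0528) but did at an FDR of 0.01, with covered bp and with the outer parts of 4 equal parts. The HPL-1 share was lower than that of HPL-2 in intestine on 6 of 6 chromosomes, by 14.2 percentage points over all (exact sign-flip test over chromosomes, p = 0.0312, the smallest that 6 chromosomes allow). The HPL-2 lists of the tissues differed by 0.0104 points (exact sign-flip p = 0.438). On chromosome V, the Mb starting at 17 Mb held 84 HPL-2 hypodermis, 65 HPL-1 intestine and 41 HPL-2 intestine peaks.

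**Figure D3:**
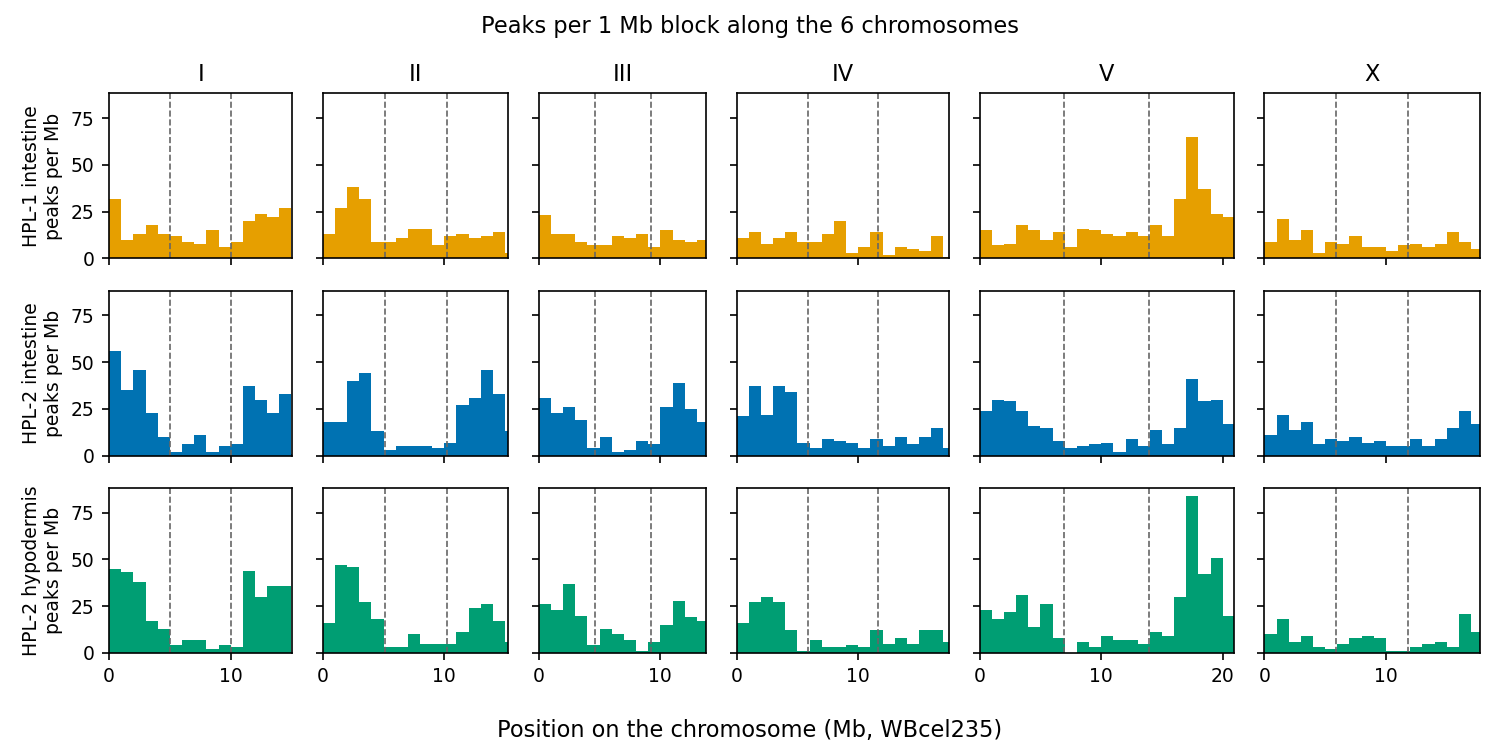
Number of peaks in each 1 Mb block (y axis) along the 6 chromosomes (x axis, Mb) for the 3 peak lists; dashed lines divide each chromosome into 3 equal parts. HPL-2 blocks are highest in the outer parts, which hold 88.3% and 88.4% of peaks, against 74.1% for HPL-1, and the highest block holds 84 hypodermis peaks on chromosome V.

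Peak numbers per chromosome were tested by rotating all peaks over the 6 chromosomes joined end to end. No chromosome as a whole held more or fewer peaks than this rotation gave, after adjustment over the 3 lists and 6 chromosomes. The X chromosome, 17.7% of the length, held 11.9% of HPL-1 intestine, 12.1% of HPL-2 intestine and 8.21% of HPL-2 hypodermis peaks, with unadjusted rotation p of 0.0216, 0.0376 and 0.0146 and an adjusted p of 0.135 for each. Protein-coding gene bodies took 75.2% of the HPL-2 intestine sequence, against 62.9% by rotation (permutation test, adjusted p = 0.00045). They took 63.8% in HPL-1 intestine (62.2% by rotation, permutation test, adjusted p = 0.332) and 66.1% in HPL-2 hypodermis (63.4%, 0.0615). Flanks within 1 kb of these genes were below rotation in every list, with 14.7% against 18.8% in HPL-1 intestine, 9.92% against 18.2% in HPL-2 intestine and 14.7% against 18.3% in HPL-2 hypodermis (permutation test, adjusted p = 0.00045 each). Sequence elsewhere was 14.9% in HPL-2 intestine, below the 18.9% of rotation (0.00108), a difference that no longer passed with 2 kb flanks (0.115). It was 21.5% in HPL-1 intestine (0.072) and 19.2% in HPL-2 hypodermis (0.414).

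Within each list, a few gene groups stood apart from rotation. In intestine HPL-2 lay over 80 of 177 cuticle collagen genes (45.2%, 37.7% to 52.8%), against 6.39 by rotation, led by col-87 (score 2.68), col-72 (2.5, under the same peak as clec-126), col-102 (1.67) and col-111 (1.64). In hypodermis it lay over 8 (4.52%, 1.97% to 8.71%), against 6.63 (permutation test, adjusted p = 1.0). Muscle genes were over-represented under HPL-2 in both tissues, with 19 of 33 in intestine (57.6%, 39.2% to 74.5%, rotation 3.99) and 18 of 33 in hypodermis (54.5%, 36.4% to 71.9%, rotation 3.85). In HPL-1 intestine 7 were bound, against 3.55 by rotation, which did not pass (permutation test, adjusted p = 0.256). The highest scoring were the myosin gene unc-54 (I, 14855901 to 14863482, scores 2.2 in intestine and 2.53 in hypodermis), the troponin T gene tnt-3 (1.74 in intestine), the obscurin-related gene unc-89 (1.72 and 2.33), the paramyosin gene unc-15 (1.69 and 2.22) and dim-1 (2.08 in hypodermis). Chemoreceptor genes were under-represented in HPL-2 intestine, with 19 of 1308 (1.45%, 0.877% to 2.26%) against 53.5, and the highest scoring of the 19 were srh-178, sre-32, srh-209 and sri-5. They were below rotation without passing in HPL-1 intestine (35 against 52.9, permutation test, adjusted p = 0.196) and HPL-2 hypodermis (47 against 66.1, 0.271). The calls for HPL-2 intestine collagens, muscle genes in both tissues and HPL-2 intestine chemoreceptors had an adjusted p of 0.0025, which derives from the smallest p the draws can give.

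C-type lectins, carbohydrate-binding proteins of which many respond to bacteria, were over-represented in HPL-1 intestine with 28 of 239 (11.7%, 7.93% to 16.5%, rotation 9.19). They were so in HPL-2 hypodermis with 35 (14.6%, 10.4% to 19.8%, rotation 12.1), with an adjusted p of 0.0025 in each. The leading members were clec-250 (1.63), clec-238 (1.53), clec-148 (0.99) and clec-149 (0.95) for HPL-1 and clec-115 (2.71), clec-101 (2.35), clec-31 (2.3) and clec-104 (2.25) in hypodermis. In HPL-2 intestine 20 were bound (rotation 10.9, permutation test, adjusted p = 0.21). HPL-1 also lay over 15 collagen genes (rotation 4.95, permutation test, adjusted p = 0.0107), led by col-3, col-87, col-94 and col-102, and 12 of 85 hedgehog-related and patched-related genes (rotation 4.76, adjusted p = 0.0487), led by grd-2, grd-11, grd-13 and ptr-23. The last group had similar numbers in HPL-2 intestine, 13 against 5.42 by rotation, without passing (permutation test, adjusted p = 0.0683), and 5 against 5.71 in HPL-2 hypodermis. The HPL-1 collagen call was lost at an FDR of 0.01 (0.0731) and by Fisher's exact test (0.0982), and the hedgehog-related call at an FDR of 0.01 (0.181) and with 1 kb added on either side of genes (0.1725).

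**Figure D4:**
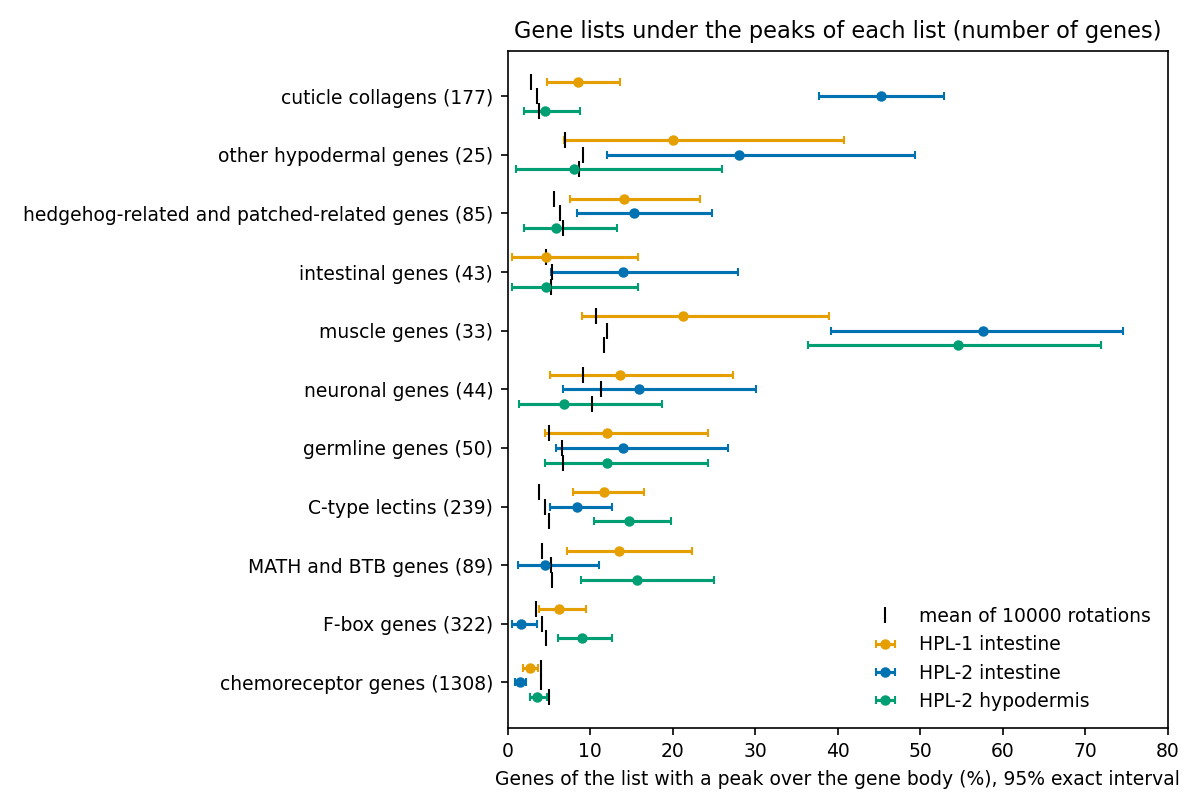
Percentage of the genes in 11 gene lists that have a peak over their body (x axis), for the 3 peak lists; points are observed shares with exact 95% intervals, black marks are the means of 10000 rotations, and the number of genes follows each name. Collagens stand at 45.2% in HPL-2 intestine against 8.47% and 4.52% in the other lists, and muscle genes at 57.6% and 54.5% in the HPL-2 lists.

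Other groups did not pass in any list, given here for HPL-1 intestine, HPL-2 intestine and HPL-2 hypodermis in turn. Among groups tied to these tissues, 2, 6 and 2 of 43 intestinal genes, 5, 7 and 2 of 25 other hypodermal genes, and 1, 0 and 0 of 22 epidermal antimicrobial peptide genes were bound. Peaks covered 0, 0 and 2 of 46 lysozyme and saposin-like genes, 6, 2 and 4 of 188 detoxification enzyme genes, and 4, 4 and 5 of 78 lipase and fatty acid genes. Of regulators, 8, 9 and 9 of 269 nuclear hormone receptor genes, 2, 6 and 8 of 88 homeobox genes, 1, 2 and 1 of 47 heterochromatin and synMuv genes, and 5, 3 and 5 of 46 small RNA pathway genes were bound. Among genes of other tissues, 6, 7 and 3 of 44 neuronal, 1, 2 and 3 of 103 neuropeptide, 6, 7 and 6 of 50 germline and 0, 3 and 0 of 31 major sperm protein genes had a peak. Peaks lay over 0, 6 and 1 of 72 histone genes, 1, 2 and 0 of 74 ribosomal protein genes, 1, 3 and 2 of 29 ER stress response genes, and 2, 3 and 1 of 36 heat shock and oxidative stress genes. F-box genes (20, 5 and 29 of 322, rotation 11.1, 13.4 and 14.9) and MATH and BTB genes (12, 4 and 14 of 89, rotation 3.69, 4.67 and 4.75) did not pass against rotation either, although they differed between lists.

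Of the genes encoding the fused proteins, hpl-2 (III, 10752195 to 10755530) had an HPL-1 intestine peak over its body (10752822 to 10754700, score 0.62, rank 804 of 1346) and no HPL-2 peak in either tissue. For hpl-1 (X, 13245390 to 13247044) there was no peak in the 3 lists.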

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

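The tests of score-matched sharing with the hypodermis and HPL-1 lists, of intestinal genes and of near-identical copies were chosen after the result they bear on was seen.

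Cuticle collagen genes differed between the tissues for HPL-2, with an odds ratio of 0.0258 for hypodermis over intestine among genes bound in only 1 of them. A few peaks over tandem genes would give few collagen peaks, but 84 HPL-2 intestine peaks on 6 chromosomes lay over collagens, and with genes under 1 peak counted once 2 stood against 73 (Fisher's exact test, adjusted p = 1.6e-17). General loss of weaker peaks in hypodermis would leave collagens shared as often as other genes of like score. Of the collagens bound in intestine, 7.5% were also bound in hypodermis, against 37.9% of score-matched genes (permutation p = 0.0002, the smallest possible). A low GFP-Dam signal over collagens in intestine would raise HPL-1 too. Of the same collagens, 10.0% were also bound by HPL-1, against 27.7% of score-matched genes (permutation p = 0.0002), while HPL-1 collagens were themselves above rotation. Genes were matched on score only and not on length, and the shared collagens are those already counted in the comparisons between lists. The values show that score alone does not account for the low sharing, and they exclude neither explanation. A high GFP-Dam signal over genes used in the same tissue could hide HPL-2 at collagens in hypodermis. It cannot be told apart from a lower HPL-2 occupancy there. Intestinal genes gave only 4 discordant cases, 4 in intestine and 0 in hypodermis (exact McNemar p = 0.125, the smallest that 4 cases allow). Other hypodermal genes (5 in intestine only, 0 in hypodermis only, Fisher's exact test, adjusted p = 0.195) went the same way as collagens without passing. So did hedgehog-related and patched-related genes (9 and 1, exact test, adjusted p = 0.0895). A tissue difference in HPL-2 binding at collagens therefore stays a hypothesis, and GC content was not tested.

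F-box genes (odds ratio 7.61), MATH and BTB genes (11.7) and chemoreceptor genes (3.65) differed between the tissues in the other direction, toward hypodermis. If the HPL-2 intestine list only had fewer peaks in the regions that hold these families, the difference would vanish within strata of chromosome and outer or central part, but 79 family genes were bound in hypodermis only, against 59.9 in strata, and 57 by HPL-1 only, against 35.9 (larger permutation p = 0.0002, the smallest possible). This argues against peak numbers in these large parts of the chromosomes as the whole cause. Smaller regions within a part were not tested and stay open, and the families were chosen by these same differences. Reads shared between near-identical copies stay open, since Fisher's exact test over the families together (larger p = 9e-10) only restates the differences by which they were chosen, and sequencing depth and control signal per tissue were not tested. A tissue difference of HPL-2 at these families may be followed up as a hypothesis, but whether it is a loss in intestine or a gain in hypodermis stays open for F-box and MATH and BTB genes, which passed against rotation in neither tissue, while chemoreceptor genes passed below rotation in intestine only (19 against 53.5, and 47 against 66.1 in hypodermis).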

How the results depend on the processing

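The alternatives with 1 kb on either side of genes, with 2 kb flanks, with peaks of 500 bp, with the arm tests adjusted together with those per chromosome and all those for HPL-1 peaks against both HPL-2 lists were chosen after the data had been seen.

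The overlaps of all 3 pairs of lists kept their direction and passed in each of their 5 alternatives, as did the lower overlap of HPL-2 intestine peaks with HPL-1 than with HPL-2 hypodermis in 4 of its 6, including a sign permutation over 1 Mb blocks (p = 0.00031). That difference no longer passed with every peak set to 500 bp around its midpoint (-2.46 points) or with lists of equal size as well (-0.297 points), settings that bring the chance overlap of the lists together. Of results that answer a comparison, 97 values under alternatives kept their direction and side of the threshold. For counts, kept means within 1.5 times the reported count. Another 3 no longer passed, 6 newly passed and 11 counts moved further. Of single gene lists and smaller results 79 were kept, 11 no longer passed, 1 newly passed and 1 reversed. Values that passed neither before nor after also count as kept. Gene lists that did not pass in the first place, such as C-type lectins between peak lists, are not in this tally. HPL-1 arms passed at an FDR of 0.01 (77.9% of peaks), with covered bp (75.6%) and with the outer parts of 4 equal parts (61.1%, rotation 49.99%), and had an adjusted p of 0.185 when adjusted over 21 tests. With 2 kb flanks, sequence elsewhere was 14.8% in HPL-1 intestine and 13.4% in HPL-2 hypodermis, both now passing, and 9.82% in HPL-2 intestine, no longer passing; flanks and elsewhere trade places by construction. At an FDR of 0.01, elsewhere in HPL-1 intestine passed (22.96%), the bound genes fell to 550 for HPL-1 intestine and 756 for HPL-2 hypodermis since fewer peaks entered, and the gene lists above rotation in HPL-1 intestine fell from 3 to 1. With Fisher's exact test against other genes, the lists above chance were 5 in HPL-1 intestine and 4 in HPL-2 intestine, and those below were 1 in HPL-1 intestine, 3 in HPL-2 intestine and 1 in HPL-2 hypodermis. Lists of equal size gave 4 above in HPL-2 intestine, rotation within parts of chromosomes gave 2 below there, and 1 kb on either side of genes gave 7 lists that differed between the HPL-2 tissues in place of 4. The difference of HPL-1 peaks between the HPL-2 lists reversed from 0.52 to -0.297 points with 50% of the peak covered, neither passing. Except where stated, the cause was not tested. No paired analysis was possible because each deposited list is an average with no values per replicate, so leaving out a replicate was not possible either. Upstream windows, exon, intron and repeat shares were not run, since the gene table has no strand, exons or repeats. The depth of the libraries is not given in the sources used here, so a gene without a peak was not detected and is not shown to be unbound.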

Other observations

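All tests in this part were chosen after the peak lists had been seen, and the muscle tests after the muscle counts.

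Among the 178 protein-coding genes bound in all 3 lists were 6 of 33 muscle genes, the muscle regulator hlh-1 and the structural genes tni-3, ttn-1, unc-22, unc-54 and unc-89. The C-type lectins clec-50, clec-78, clec-101, clec-115, clec-126 and clec-250 were also among them, as were the collagens col-87 and col-102 and the hedgehog-related or patched-related genes grd-2, grd-11 and ptr-23. Members of other groups included the chemoreceptor genes sre-32, srh-178 and sri-5, the F-box gene fbxb-35, the MATH and BTB gene bath-29, and jph-1 and unc-44 from the neuronal gene list. The nuclear hormone receptor gene nhr-239, the ER stress response gene dnj-27, the forkhead factor gene daf-16, the small RNA gene eri-6 and the molting gene mlt-11 were also bound in all 3 lists.

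Genes that do not code for proteins were unevenly covered. Of 15363 piRNA genes, which lie mostly in clusters on chromosome IV, 17 were under HPL-1 intestine, 13 under HPL-2 intestine and 26 under HPL-2 hypodermis peaks, against 107, 171 and 182 by rotation (permutation test, adjusted p = 0.0016 each, from the smallest p the draws can give). Pseudogenes were above rotation in HPL-1 intestine (121 of 1921, rotation 63.3, permutation test, adjusted p = 0.0024) and HPL-2 hypodermis (129, rotation 82.7, 0.0136) but not in HPL-2 intestine (77, rotation 73.1, 1.0), and the difference between lists was not tested. Genes annotated as ncRNA were above rotation in HPL-2 intestine (167 of 7762, rotation 117, permutation test, adjusted p = 0.0136) and miRNA genes in HPL-2 hypodermis (13 of 260, rotation 4.39, 0.0453). All these tests rotated over whole chromosomes, and rotation within parts of chromosomes was not run for them. The uneven density of peaks along chromosomes was therefore not taken into account, for piRNA genes and pseudogenes as well.

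A scan of 133 gene families defined by symbol, 399 tests with 50000 rotations, found 0 families past the threshold after adjustment and 10 tests with an unadjusted p below 0.05. A first run with 10000 rotations also found 0. Both results hold for the scanned families only. Cuticle collagens in HPL-2 intestine (80 bound, rotation 6.39) and C-type lectins in HPL-1 intestine (28, rotation 9.19) passed as gene lists above (permutation p = 0.0002 each). Symbol families made up largely of members of the gene lists tested above were left out of the scan by design. Collagens and C-type lectins were therefore not scanned, and the 0 says nothing about them. Among the scanned families, the lowest unadjusted p was that of the lido family in HPL-2 intestine, with 8 of 17 genes bound against 0.828 (permutation p = 0.0004, adjusted p = 0.16), and 5 were bound in HPL-1 intestine and 6 in HPL-2 hypodermis.

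Muscle genes lay under HPL-2 peaks in both tissues, neither of which is muscle. Their length, with a median of 5219 bp against 2006 bp for protein-coding genes, could raise the count, but the highest count in 10000 draws of length-matched genes was 12 in intestine and 11 in hypodermis, with means of 3.57 and 3.32, against 19 and 18 observed. Extra copies of unc-54 sequence in transgenes would concern 1 gene, but 18 other muscle genes in intestine and 17 in hypodermis were bound, which says nothing of transgenes that carry other muscle gene sequence. These values argue against length and unc-54 copies as the whole cause, while GC content and the GFP-Dam signal over muscle genes were not tested. That HPL-2 may mark muscle genes in intestine and hypodermis stays a hypothesis.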
